A study of Mus musculus with 9 samples.

How the data were processed

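Total RNA of 9 mouse lungs was hybridised to Affymetrix whole-transcript arrays, 3 per group. Per the submitters' processing notes, Affymetrix Power Tools and R 3.5.1 were used, and the normalization method is not given in the sources used here. The value table that the authors deposited holds log2 signals of 41345 probe sets, as judged from their range of 0.91 to 13.68, with no missing value. The array medians lay between 4.49 and 4.57, the lower quartiles between 3.21 and 3.24 and the upper between 5.91 and 6, so the arrays had been brought to a common scale before deposit. How strongly that step shrinks or shares signal between arrays cannot be seen from the values. No detection call was used here, so dim probe sets were kept, and control probe sets were not separated from the rest.

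The authors' tables of the 3 comparisons give, per the file headers, a signed linear fold change, a score (the LPE statistic, a local pooled error test) and adjusted p-values for listed probe sets. The log2 values that the authors list were checked against the value table, and 0 differed by over 1e-06. The deposited fold changes were not recomputed here from the group means of these values. The deposited p-values are from the LPE test, which pools error across genes of like signal. The smallest absolute folds were 1.5, 1.594 and 1.551, and the largest adjusted p-values 0.0498, 0.0497 and 0.05, so the listing required both. The authors' pathway tables hold counts of listed genes with p-values and false discovery rates. Their background is not tested here.

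Gene names come only from the authors' comparison tables, which list 2129 probe sets. Of these 2010 have a symbol, for 1908 genes, 4.86% of the probe sets on the array. The other probe sets are unnamed here, and a name therefore means that the authors found a change in at least 1 comparison. The planned test of named genes only would have adjusted p over genes already chosen on these arrays. For this reason every probe set was tested on its own and adjusted over all 41345, and the fit on named genes alone was kept as an alternative. This change was made after the values and exploratory fits had been seen. Of the listed probe sets 381 are of cross-hybridisation type 3, per the file headers. The genome build is not given in the sources used here. Of 1753 listed probe sets whose gene identifier is in the RefSeq genes of GRCm38.p6, 1709 (97.49%) overlap the gene there. Symbols were kept as in the files.

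Tests used limma 3.58.1 in R 4.3.3. A model of group means was fitted to all 9 arrays, with 6 residual degrees of freedom, followed by eBayes, 2-sided tests and Benjamini-Hochberg adjustment within each comparison, at a threshold of 0.05. The prior gave 2.66 degrees of freedom. Folds are 2 to the power of the absolute log2 difference of group means. An exact test on 3 against 3 arrays cannot go below 0.1, so no rank or permutation test of single genes was made.

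Before the data were examined, 39 gene lists were fixed from textbook knowledge. Members were counted among named genes, each gene taken at its probe set with the highest mean, and 24 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, against the other named genes. Camera with an estimated correlation and the rotation test fry stood beside it. No list was called with the estimated correlation in any comparison, while fry, which compares a list with no other genes, called 22, 16 and 16 lists. A naming rule set which genes the text could single out. These were, per comparison, the 15 largest rises and 15 largest falls among genes past the threshold whose arrays do not overlap between the groups. The 4 members of each list with the smallest p were added. Predicted genes, small RNA genes and receptor segments were left out and numbered 232, 1 and 22 among the called genes of the 3 comparisons. Of all probe sets, 28%, 14% and 21.1% had arrays that did not overlap between the groups, where chance gives 10%.

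The share of the bleomycin change remaining was the slope through 0 of the homoharringtonine change on the bleomycin change, over 9 choices of 1 bleomycin and 1 vehicle array held out. Probe sets were chosen from the other arrays, where fewer than 100 were called, so the 100 with the smallest p were used. A corrected slope used the change in the choosing arrays as an instrument. Effects shared between comparisons were set against 20 simulations of unchanged groups.

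The scripts were tested on simulated data made from the real means and spreads of 41345 probe sets, with 200 changed. For bleomycin against vehicle 0% were recovered at a log2 change of 0.5, 65.5% at 1 and 97.5% at 2. For homoharringtonine against bleomycin these were 0%, 66.5% and 95%, and for homoharringtonine against vehicle 0%, 63% and 98%. A simulated share of 0.5 came back as 0.499. Alternatives covered 2-group fits, a trended robust prior, array weights, quantile normalization, median centring, a filter on dim probe sets, a replicate block, leaving out each array, other thresholds and the authors' lists. The mean of the probe sets of a gene was tried for named genes only, since the others have no name to group them by.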

Results

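Gene expression was measured on Affymetrix arrays in whole lung tissue of 9 male C57BL/6J mice, in 3 groups of 3. Bleomycin, a DNA-breaking antibiotic used to induce lung fibrosis in rodents, was instilled into the trachea at 2 U/kg at 8 weeks of age. Homoharringtonine is a plant alkaloid that blocks the elongation step of translation. It was injected into the peritoneum at 0.545 mg/kg from day 5, 2 times a week for 15 days, and the lungs were from mice of 11 weeks. The groups were vehicle-treated mice, bleomycin-instilled mice, and bleomycin-instilled mice given homoharringtonine. The sample labels give the same injection schedule for the vehicle and bleomycin mice, with no homoharringtonine dose. Each array held log2 signals of 41345 probe sets, with medians from 4.49 to 4.57. The number of arrays, 3 per group, limits the precision of every value. No pair of arrays held identical values.

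On the leading principal component, which held 33.9% of the variance, the vehicle arrays lay from -56.1 to -33.2. The bleomycin arrays lay at 16, 48.4 and 46.6, and the arrays with homoharringtonine at 2.5, 2.8 and 21.5. The second component held 13.7% of the variance and placed the homoharringtonine arrays from -41.1 to -14.6, below all other arrays. Bleomycin replicate 1 was the bleomycin array nearest to the homoharringtonine group on the leading component.

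**Figure D1:**
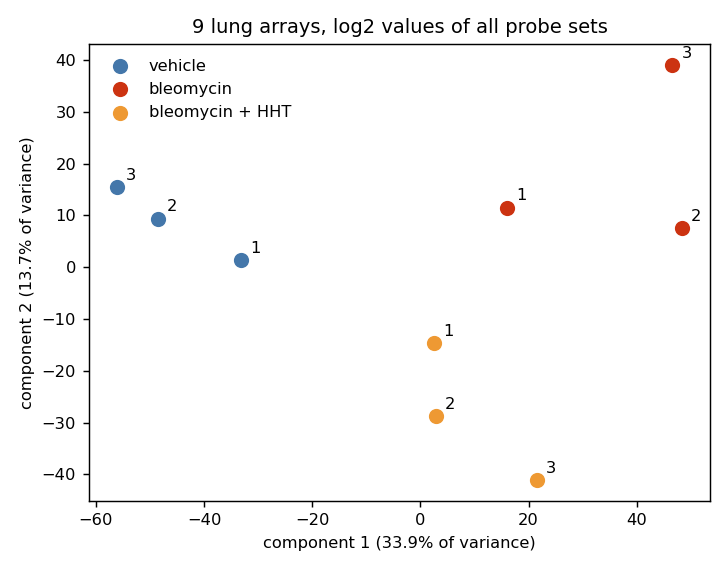
Scores of the 9 arrays on the leading principal components of the log2 values, with the share of variance on each axis. Colours are the groups and digits the replicate numbers. The vehicle arrays, at -33.2 or below on the horizontal axis, lie apart from both bleomycin groups, and the homoharringtonine arrays lie lowest on the vertical axis.

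The comparison of bleomycin with vehicle asked how the injured lung differed from the control lung. Matrix and macrophage genes were among those with the largest rises. Saa3, an acute-phase protein, was 31.2-fold higher, and Spp1 (osteopontin, a matrix and macrophage glycoprotein) was 23.3-fold higher. The Spp1 signal was 6.88 ± 0.17 (SD, n = 3) in vehicle and 11.42 ± 0.47 (SD, n = 3) in bleomycin, with an adjusted p of 0.000224. Spp1 (gene 20750) lies on chromosome 5 from 104435111 to 104441053 and Lrat (gene 79235) on chromosome 3 from 82892579 to 82903974, by the coordinates in the authors' tables, whose genome build is not given in the sources used here. The matrix glycoprotein tenascin C (Tnc) rose 13.9-fold, the metalloproteinase inhibitor Timp1 12.8-fold, and the metal-binding Mt2 and the arginine-degrading Arg1 12.4-fold each. The largest fall of a named gene was in Lrat, which esterifies retinol for storage in lipid-holding cells. Its log2 signal went from 8.66 ± 0.05 to 5.28 ± 0.2 (SD, n = 3 each), 10.4-fold lower, with an adjusted p of 0.000519. Over the array, limma called 3218 of 41345 probe sets at an adjusted p under 0.05, of which 1392 were higher and 1826 lower with bleomycin. This balance depends on the scaling, since 1581 were higher and 1558 lower after median centring. All 3218 had arrays that did not overlap between the groups, as 28% of all probe sets did, where chance gives 10%. Among them were 1529 named genes, 636 higher and 893 lower.

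Other large rises were in Chl1 (10.2-fold), the type 2 immune effector Retnla (9.2-fold), the macrophage glycoprotein Gpnmb (9.18-fold) and the scavenger receptor Msr1 (8.79-fold). The collagen cross-linking enzyme Lox rose 6.85-fold, Cd109 6.66-fold, Wfdc17 6.53-fold, the collagen-degrading protease Ctsk 6.45-fold, and elastin (Eln) 6.25-fold. Among the falls were Acoxl (7.05-fold), the complement component Hc (6.96-fold), the lysozyme Lyz1 (6.33-fold), Car3 (6.3-fold), the killer-cell granzyme Gzma (6.23-fold) and the B cell surface protein Ms4a1 (5.99-fold). Kcnj13 fell 5.87-fold, the death ligand Tnfsf10 5.8-fold, the incretin receptor Glp1r 5.44-fold, Aox3 5.08-fold, the interferon-induced Gbp4 4.95-fold, Arhgef38 4.7-fold and the eosinophil-type ribonuclease Ear1 4.69-fold. The vomeronasal receptor gene Vmn2r8 fell to a log2 signal of 2.02, below the lower quartile of every array, so no fold is given. The folds of Chl1 and Gzma rest on mean log2 signals of 3.4 in vehicle and 3.41 in bleomycin lungs, near the lower quartile of the arrays. Other folds also rest on dim signals. Among them are Cd109 (vehicle arrays 3.56, 4.01 and 3.36) and, given below, Il1r2 (vehicle 3.87, 3.7 and 3.63) and Ncr1 (bleomycin 3.59, 3.25 and 3.71). Saa3 was dim in vehicle (4.12, 4.03 and 3.68) and spread widely over the bleomycin arrays (8.84, 10.02 and 7.86). The homoharringtonine arrays were dim for Tat (3.96, 4.22 and 4.29), Serpina3m (4.27, 4.23 and 4.29) and Adm (4.29, 4.12 and 4.33), whose folds are given below.

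**Figure D2:**
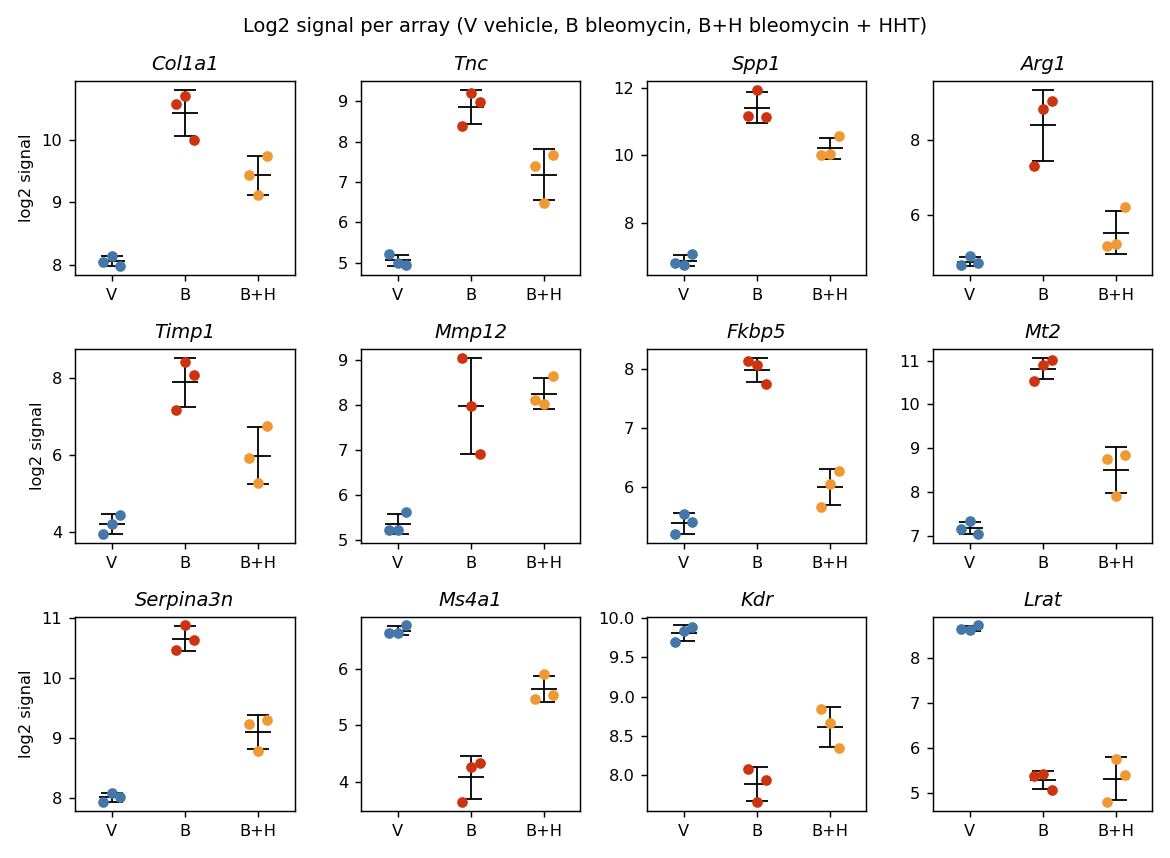
Log2 signal of 12 named genes on each of the 9 arrays. Points are mice, and the bars give the mean and SD of the 3 arrays in a group. Spp1 goes from 6.88 in vehicle to 11.42 in bleomycin and 10.22 with homoharringtonine, Fkbp5 from 5.39 to 7.99 and 6, and Lrat from 8.66 to 5.28 and 5.31.

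Of the 24 lists tested, camera called 14 for bleomycin against vehicle, and 0 with an estimated correlation. Genes of the extracellular matrix rose together. Of 30 genes in that list 23 were measured under a name, 19 of them rose and none fell (23 rose adjusted over the list alone). Col1a1, a chain of the main fibrillar collagen, rose 5.12-fold and fibronectin (Fn1) 5.95-fold. All 10 measured matrix proteases and inhibitors rose (10 adjusted over the list alone), with Mmp19 up 2.96-fold and Mmp14 3.54-fold. All 7 measured targets of TGF-beta rose (7 adjusted over the list alone), with Ctgf up 4.58-fold and Tgfbi 3.42-fold. In the myofibroblast list 4 of 5 measured members rose (5 adjusted over the list alone), including smooth muscle actin (Acta2, 2.14-fold) and Tagln (2.29-fold). Against the other named genes, camera gave adjusted p values of 1.11e-07 for the matrix list, 0.000544 for proteases, 0.00341 for TGF-beta targets and 0.0237 for the myofibroblast list. With an estimated correlation these were adjusted p = 0.365, 0.365, 0.365 and 0.38.

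Markers of recruited macrophages rose as a group, while those of resident alveolar macrophages went both ways. All 20 measured members of the monocyte-derived macrophage list rose (20 adjusted over the list alone), among them Trem2 (3.25-fold), Cd63 (2.83-fold) and Gpnmb, with a camera adjusted p of 1.11e-07, and adjusted p = 0.365 with an estimated correlation. Of 10 measured alveolar macrophage genes, 2 rose and 4 fell (5 and 5 adjusted over the list alone), with Ear1 4.69-fold lower and Ccl6 2.4-fold higher. That list had a camera adjusted p of 0.873, and its mean log2 change of -0.11 and the direction of the test, upward, differed in sign. In the complement list 5 of 8 measured members rose and 1 fell (5 and 2 adjusted over the list alone), with C1qb 6.05-fold and C1qa 4.48-fold higher. Camera gave it an adjusted p of 0.0482, and adjusted p = 0.38 with an estimated correlation. C1qa, C1qb and C1qc are also in the monocyte-derived macrophage list, so these lists are not separate evidence in any comparison. Other lists share members too, such as Mmp14 (proteases and macrophages) and Cdkn1a (p53 targets and transitional epithelium). Of 7 measured neutrophil genes 3 rose (7 adjusted over the list alone), and Il1r2, Lcn2 and Mmp8 were 4.33-fold, 2.65-fold and 2.59-fold higher. The neutrophil list had a camera adjusted p of 0.0224, and adjusted p = 0.38 with an estimated correlation. In the cytokine and chemokine list 6 of 11 measured members rose and 2 fell (9 and 2 adjusted over the list alone). Ccl9 rose 3.93-fold and the alarmin Il33 fell 2.57-fold. That list had a camera adjusted p of 0.0332, and adjusted p = 0.38 with an estimated correlation.

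Genes of NK cells fell, as did several of B cells. All 5 measured NK cell genes fell (5 adjusted over the list alone), with Ncr1 3.43-fold lower, and 5 of 8 measured B and plasma cell genes fell with none rising (1 rose and 5 fell adjusted over the list alone). The B cell transcription factor Pax5 fell 3.03-fold and Cd79a 2.3-fold. The camera adjusted p was 0.0332 for NK cells and 0.127 for B and plasma cells, and adjusted p = 0.38 for each with an estimated correlation. All 8 measured interferon response genes fell (8 adjusted over the list alone), with Ifi44 2.06-fold lower, a camera adjusted p of 0.0332, and adjusted p = 0.38 with an estimated correlation.

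Endothelial genes fell, as did most measured genes of the alveolar and airway epithelium. Of 20 measured vascular endothelial genes 16 fell and none rose (19 fell and 1 rose adjusted over the list alone). The VEGF receptor Kdr was 3.81-fold lower and Calcrl 2.46-fold lower. Camera gave that list an adjusted p of 0.00195, and adjusted p = 0.38 with an estimated correlation. In the list of type 2 alveolar epithelium 7 of 8 measured genes fell and 1 rose (7 and 1 adjusted over the list alone), with the lamellar body protein Lamp3 2.8-fold lower. In that of type 1 epithelium 4 of 5 fell (5 adjusted over the list alone), with Rtkn2 4.08-fold lower. The club cell enzyme Cyp2f2 was 4.07-fold lower. The club cell list had 3 of 5 measured members that fell, the ciliated cell list 5 of 7, and resident fibroblasts 7 of 9 with 1 that rose (5 of 5, 7 of 7, and 8 with 1 rise, adjusted over the list alone). Camera did not call these lists, with adjusted p values of 0.123 for type 2 cells, 0.0671 for type 1 cells, 0.0798 for club cells, 0.0555 for ciliated cells and 0.0507 for resident fibroblasts. Genes of the transitional epithelial state seen after injury rose in 9 of 11 cases and fell in 1 (10 and 1 adjusted over the list alone). Cldn4 rose 5.89-fold and the cell cycle inhibitor Cdkn1a 2.96-fold. That list had a camera adjusted p of 0.00626, and adjusted p = 0.38 with an estimated correlation.

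**Figure D3:**
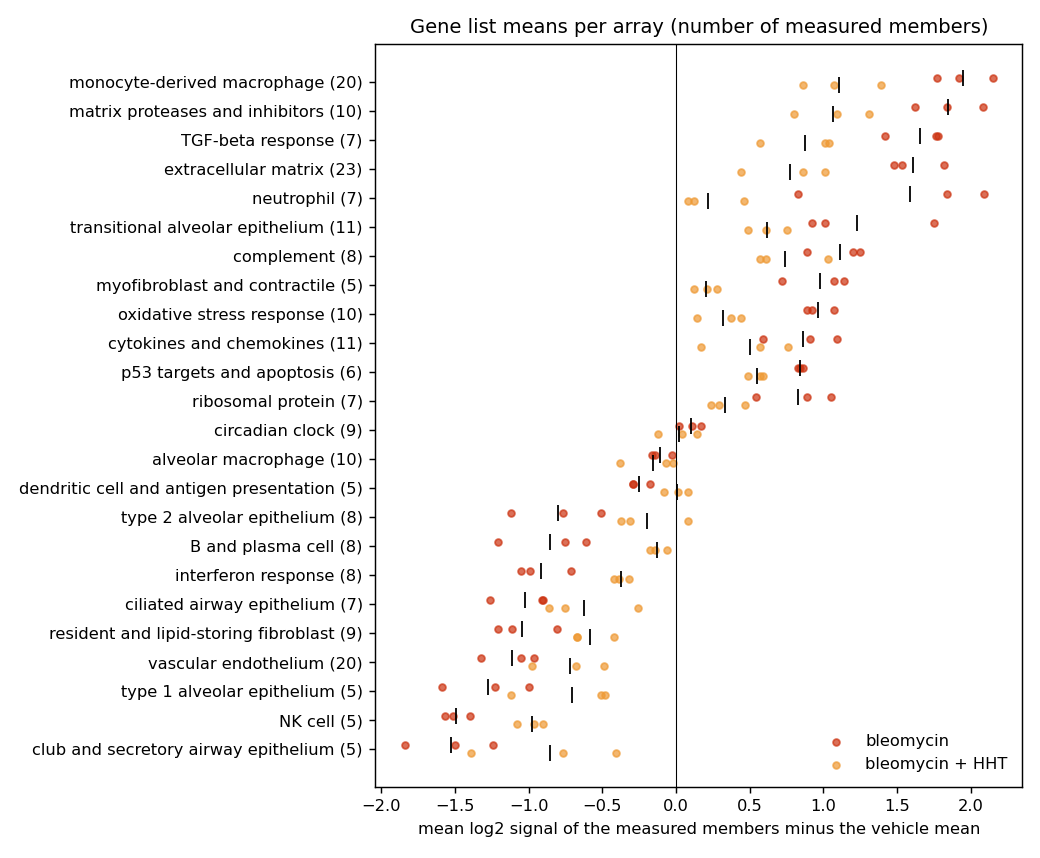
Mean log2 signal of the measured members of each gene list on each bleomycin and homoharringtonine array, after subtraction of the vehicle group mean. Points are arrays, ticks are group means, and the number of measured members stands in parentheses. The matrix list lies at 1.61 in bleomycin and 0.77 with homoharringtonine, and most other lists also have their homoharringtonine points between vehicle and bleomycin.

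Among stress and growth lists, 7 of 10 measured oxidative stress genes rose and 3 fell (7 and 3 adjusted over the list alone), with Mt1 5.28-fold higher, and a camera adjusted p of 0.0507. All 7 measured ribosomal protein genes rose (7 adjusted over the list alone), Rpl32 1.9-fold, with a camera adjusted p of 0.0177, and adjusted p = 0.38 with an estimated correlation. Only 7 of the 47 genes of that list carried a name here, and a name required that the authors listed the gene as changed. The count therefore covers members already chosen for a change and does not describe the list as a whole. Of 6 measured p53 targets 5 rose (6 adjusted over the list alone), with Bax 1.63-fold higher, a camera adjusted p of 0.0224, and adjusted p = 0.365 with an estimated correlation. All 4 measured genes of the unfolded protein and amino acid stress list, which holds 27 genes, rose (4 adjusted over the list alone). Ddit4 was 3.93-fold and Slc7a5 3.96-fold higher. All 4 measured cell cycle genes, of 32 in the list, rose (4 adjusted over the list alone), with Mki67 2.05-fold and Cdk1 2.31-fold higher. The limit given for the ribosomal protein genes holds for these lists too. Of cardiac muscle markers 4 were measured, and Myl7 and Pln fell 2.48-fold and 2.21-fold (4 fell adjusted over the list alone).

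In the authors' deposited table for this comparison 2074 probe sets were listed, 907 higher and 1167 lower with bleomycin, all with an absolute fold of at least 1.5. The authors' deposited table of pathways led with metabolic pathways (128 of 1554 genes) and PI3K-Akt signaling (62 of 356 genes), each with an FDR of 3e-26, and gave 29 of 88 genes in ECM-receptor interaction (FDR 7.39e-18) and 43 of 201 in focal adhesion (FDR 7.21e-21). As names exist only for the probe sets that the authors listed as changed on these arrays, counts of list members are not independent evidence of direction, and camera compared lists only with other changed genes. The count of calls was 2109, 1252 and 1136 without vehicle replicates 1, 2 and 3, 1380 without bleomycin replicate 2 and 1690 without bleomycin replicate 3.

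The comparison of bleomycin plus homoharringtonine with bleomycin asked what the drug changed in the injured lung. The called genes moved against their bleomycin change. Fkbp5, Mt2, Serpina3m and Serpina3n were among those lower, and the lysozyme Lyz1 and B cell gene Ms4a1 among those higher. Fkbp5 (gene 14229, chromosome 17 from 28399095 to 28517524), a co-chaperone of steroid receptors that glucocorticoids induce, was 3.96-fold lower, with a log2 change of -1.98 (SE 0.18) and an adjusted p of 0.0175. Ms4a4a was 5.17-fold lower, Mt2 4.98-fold, the acute-phase protease inhibitors Serpina3m and Serpina3n 4.39-fold and 2.92-fold, the activin inhibitor Fst 3.95-fold, the tyrosine-degrading Tat 3.91-fold and the leukocyte integrin Itgam 3.1-fold. Lyz1 was 4.02-fold higher (adjusted p 0.0175) and Ms4a1 2.94-fold higher (adjusted p 0.0448). Over the array, limma called 39 probe sets, 16 higher and 23 lower with homoharringtonine, of which 30 had a gene name. After quantile normalization 16 were higher and 17 lower. A fit on only the 6 arrays of these groups called 0, so the 39 calls depend on a spread estimated with the vehicle arrays included. All 39 had arrays that did not overlap between the groups, as 14% of all probe sets did, where chance gives 10%.

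The other named falls were the vasodilator peptide Adm (2.54-fold), Olfr920 (2.51-fold), Peg3 (2.46-fold), the mitochondrial kinase Pdk4 (2.25-fold), the kinases Map3k6 (2.23-fold) and Sgk1 (2.11-fold), and Myrip (2.03-fold). The other named rises were Car8 (2.21-fold), Dzip3 (2-fold), the ribonuclease Rnase6 (1.99-fold), Calcrl (1.88-fold), Trmt1l (1.81-fold), Senp7 (1.77-fold) and Krt23 (1.59-fold). All 39 probe sets had a difference of the other sign between bleomycin and vehicle, and 38 of these were called there. Because both comparisons use the same bleomycin arrays, their fold changes correlate with no effect at all. Over all probe sets the correlation was -0.595 against -0.499 in simulated unchanged groups, and the covariance was -0.0717 against -0.0211. The simulated groups held no bleomycin change, so their correlation is not the value for a bleomycin change that homoharringtonine left alone. Independent lists of these sizes would share 1.48 probe sets of opposite sign, a figure that leaves the shared arrays out of account. The overlap was not counted on separate bleomycin arrays, so part of it may come from the shared ones.

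Camera called 12 of the 24 lists, 9 lower and 3 higher, and 0 with an estimated correlation. It again compared lists only with other genes listed as changed on these arrays. Of the probe sets called for bleomycin against vehicle, 94.3% had a difference of the other sign here, and both comparisons use the same bleomycin arrays. Lists of risen genes were therefore likely to come out lower, and lists of fallen genes higher. The calls do not show an effect on a list beyond that on risen or fallen genes at large. Most matrix genes had lower values than with bleomycin alone without passing the threshold over all probe sets. Of 23 measured matrix genes none passed over all probe sets (19 were lower adjusted over the list alone). In every comparison, counts adjusted over a list alone cover genes already chosen for a change on these arrays. Such counts may be too high. Lox, at a log2 change of -1.95, had an adjusted p of 0.064. The mean log2 signal of the list was 8.3 ± 0.18 (SD, n = 3) in bleomycin and 7.46 ± 0.3 (SD, n = 3) with homoharringtonine, against 6.69 ± 0.04 (SD, n = 3) in vehicle. For the matrix list camera gave an adjusted p of 5.58e-08, and adjusted p = 0.247 with an estimated correlation. In the myofibroblast list none of 5 passed (5 adjusted over the list alone). Acta2 had a log2 change of -1.04 and an adjusted p of 0.0791, and its signal of 8.17 ± 0.16 (SD, n = 3) lay close to the 8.11 ± 0.25 (SD, n = 3) of vehicle. None of 7 TGF-beta targets and none of 10 proteases and inhibitors passed (4 and 8 adjusted over the list alone). Camera gave adjusted p values of 0.00485 for the myofibroblast list and for TGF-beta targets and 0.00291 for proteases, and adjusted p = 0.247 for each with an estimated correlation.

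Among immune lists, 1 of 20 measured genes of monocyte-derived macrophages was called, Itgam (16 lower adjusted over the list alone), with a camera adjusted p of 4.37e-07. Arg1 had a log2 change of -2.86 with an adjusted p of 0.0682, while Mmp12 had one of 0.27. None of 7 neutrophil genes passed (5 adjusted over the list alone). Retnlg and S100a9 had log2 changes of -2.42 and -1.75 over a wide spread between the bleomycin mice, whose SD was 1.47 for Retnlg, and the camera adjusted p was 0.00638. Of 8 measured B and plasma cell genes Ms4a1 was called (6 higher adjusted over the list alone), with a camera adjusted p of 0.037. For these lists adjusted p = 0.247 with an estimated correlation. Of 8 interferon response genes none passed (6 higher adjusted over the list alone), and Irf1 had a log2 change of 0.63. Camera gave the interferon list an adjusted p of 0.0111, and adjusted p = 0.247 with an estimated correlation. Of 20 vascular endothelial genes Calcrl was called (8 higher and 1 lower adjusted over the list alone), with a camera adjusted p of 0.0111, and adjusted p = 0.459 with an estimated correlation. None of 11 transitional epithelial genes passed (7 lower adjusted over the list alone), with the same camera adjusted p of 0.0111 and adjusted p = 0.459 with an estimated correlation.

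The measured members of the ribosomal protein and oxidative stress lists also lay lower on average. Only 7 of the 47 ribosomal protein genes carried a name, so this does not describe that list as a whole. The list of p53 targets was not called (camera adjusted p 0.135), and the unfolded protein list, with 4 measured, was not tested. None of 7 measured ribosomal protein genes passed (5 lower adjusted over the list alone), and Rpl32 had a log2 change of -0.67. For this list camera gave an adjusted p of 0.0111, and adjusted p = 0.422 with an estimated correlation. Mt2 was called among 10 oxidative stress genes (7 lower and 1 higher adjusted over the list alone), again with a camera adjusted p of 0.0111 and adjusted p = 0.247 with an estimated correlation. None of 4 measured cell cycle genes passed (0 adjusted over the list alone). Mki67 had a log2 change of -0.01 and Top2a one of 0.42.

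For this comparison the authors' deposited list held 116 probe sets, 50 higher and 66 lower, and their pathway table led with 8 of 92 genes in complement and coagulation cascades (FDR 1.01e-07). In place of 39, limma called 0 probe sets without any of the vehicle replicates 1, 2 or 3, without bleomycin replicate 2, or without homoharringtonine replicates 1 or 2, it called 1 without bleomycin replicate 3, 20 without homoharringtonine replicate 3, and 181 without bleomycin replicate 1. With all 9 arrays the count at an unadjusted p under 0.05 was 4609, where chance alone gives 2067.

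The comparison of bleomycin plus homoharringtonine with vehicle asked what still differed from the control lung. Macrophage and matrix genes were among those with the largest rises. Spp1 was at 10.22 ± 0.32 (SD, n = 3), a log2 change of 3.34 (SE 0.24) with an adjusted p of 0.00245. The macrophage elastase Mmp12 had a log2 change of 2.9 (adjusted p 0.0441), Retnla 2.88 (adjusted p 0.00848), Gpnmb 2.16 (adjusted p 0.0124), Tnc 2.12 (adjusted p 0.0359) and Ctsk 2.01 (adjusted p 0.0308). Lrat was at 5.31 ± 0.48 (SD, n = 3), against 5.28 with bleomycin alone, a log2 change of -3.35 with an adjusted p of 0.00112. Over the array, limma called 209 probe sets, 80 higher and 129 lower, which held 143 named genes. After quantile normalization the calls were nearer to balance, with 103 higher and 113 lower. All 209 had arrays that did not overlap between the groups, as 21.1% of all probe sets did.

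Other rises were in the lectin Clec4n (log2 change 2), the chemokine Ccl9 (1.6), Lrg1 (1.54), Fn1 (1.53), the anion exchanger Slc26a4 (1.46), AA467197 (1.46) and the lysosomal protease Ctss (1.45). The Tmem254b and Plac9b probe sets on chromosome 14 were higher by log2 changes of 2.22 and 1.62. These probe sets are of cross-hybridisation type 3, so copies of a gene in this region are not separate measurements. Besides Lrat, the largest falls were in the clock transcription factor Arntl, at a log2 change of -2.26 (adjusted p 0.000475), Gzma at -1.98, Acoxl at -1.9, the inducible chaperones Hspa1b at -1.79, Hsph1 at -1.71 and Hspa1a at -1.38, Igfbp3 and Kcnj13 at -1.71 each, and the paraoxonase Pon1 at -1.69. Scube2 (-1.54), Adgre4 (-1.52), the cysteine-forming enzyme Cth (-1.44), Slc5a12 (-1.43) and Spon2 (-1.43) were also lower. Igfbp3, Cth and Slc26a4 had not passed the threshold for bleomycin against vehicle, at adjusted p values of 0.0853, 0.189 and 0.0549, nor did they between homoharringtonine and bleomycin alone, at 0.0682, 0.0597 and 0.115.

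**Figure D4:**
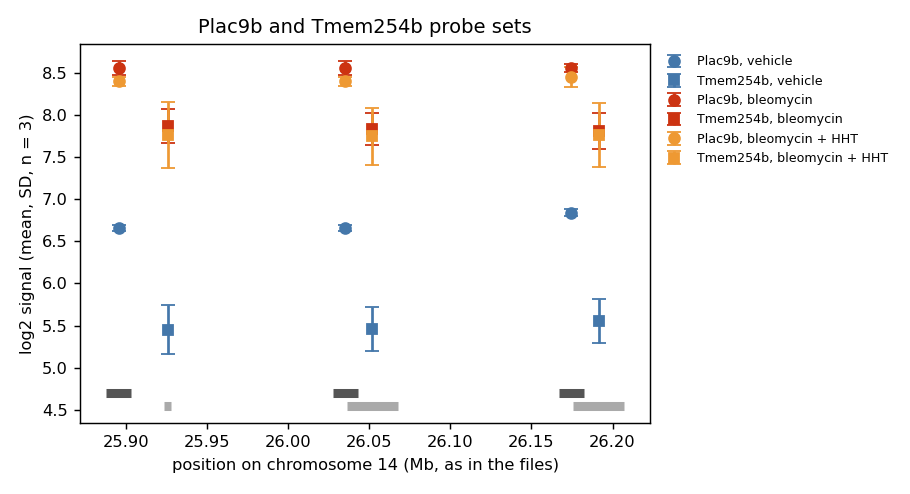
Log2 signal of the 3 Plac9b and 3 Tmem254b probe sets against their position on chromosome 14. Points are group means with SD over 3 arrays, and the grey bars give the span of each probe set, dark for Plac9b and light for Tmem254b. The mean of the 6 probe sets is 6.1 in vehicle, 8.2 in bleomycin and 8.09 with homoharringtonine.

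Camera called 10 of the 24 lists, 8 higher and 2 lower, and 0 with an estimated correlation. The named genes had been chosen for a change on these arrays, and the vehicle arrays are shared with bleomycin against vehicle. The camera calls and the counts adjusted over a list alone are therefore not independent evidence. Of the lists, 8 of 20 measured genes of monocyte-derived macrophages rose (15 adjusted over the list alone), among them Trem2, Cd63, C1qa and C1qb, with log2 changes of 1.12, 1, 1.34 and 1.42. Camera gave this list an adjusted p of 7.41e-08. Of 23 matrix genes 3 rose, Fn1, Tnc and Col1a1 (17 adjusted over the list alone), with a camera adjusted p of 7e-07. Of 10 proteases and inhibitors 3 rose (6 adjusted over the list alone), with a camera adjusted p of 0.000755, and of 7 TGF-beta targets Ctgf rose (5 adjusted over the list alone), with a camera adjusted p of 0.00406. For these lists adjusted p = 0.466 with an estimated correlation. None of 5 myofibroblast genes passed (1 adjusted over the list alone), and the camera adjusted p was 0.258. In the cytokine list 2 of 11 rose, Ccl6 and Ccl9 (4 rose and 1 fell adjusted over the list alone), in the complement list 2 of 8, C1qa and C1qb (6 and 1 adjusted over the list alone), and none of 11 transitional epithelial genes passed (5 higher and 1 lower adjusted over the list alone). Their camera adjusted p values were 0.03, 0.0194 and 0.0132, and adjusted p = 0.499 for each with an estimated correlation. Of 10 alveolar macrophage genes Ccl6 rose and Fabp1 fell (3 and 4 adjusted over the list alone), with a camera adjusted p of 0.991 and a mean log2 change of -0.15, which differs in sign from the upward direction of the test. Of 7 neutrophil genes Lcn2 rose (1 adjusted over the list alone), with a camera adjusted p of 0.274.

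Of 20 vascular endothelial genes 4 fell (16 adjusted over the list alone), Kdr, Tek, Flt1 and Ednrb, at log2 changes of -1.2, -0.92, -0.85 and -1.37. For the endothelial list camera gave an adjusted p of 0.000755, and adjusted p = 0.499 with an estimated correlation. Of 5 NK cell genes Gzma fell (5 adjusted over the list alone), with a camera adjusted p of 0.0234 and adjusted p = 0.499 with an estimated correlation. Among p53 targets Ccng1 rose (4 of 6 adjusted over the list alone), at a log2 change of 0.88, with a camera adjusted p of 0.0154 and adjusted p = 0.466 with an estimated correlation. Top2a rose among 4 cell cycle genes (4 adjusted over the list alone), at 1.3.

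Of the 209 probe sets, 185 were also called for bleomycin against vehicle in the same direction and 0 in the other. Independent lists would share 8.39, a figure that leaves the shared vehicle arrays out of account. The correlation of the fold changes was 0.725 against 0.501 in simulated unchanged groups, which held no bleomycin change, and the covariance 0.102 against 0.0212. The overlap was not counted on separate vehicle arrays, so part of it may come from the shared ones. The authors' deposited list held 294 probe sets for this comparison, 152 higher and 142 lower. The count of limma calls was 69, 13 and 7 without vehicle replicates 1, 2 and 3, 97 without bleomycin replicate 2, and 122, 113 and 14 without homoharringtonine replicates 1, 2 and 3.

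How much of the bleomycin change remained with homoharringtonine was measured on arrays that had no part in choosing the probe sets. Over 9 choices of held-out arrays, 100 probe sets each, the median slope of the homoharringtonine change on the bleomycin change was 0.6, with a range from 0.51 to 0.63. Corrected for noise it was 0.621, from 0.52 to 0.712. All 9 choices used the same 3 homoharringtonine arrays, so these ranges leave out the spread between those mice. Over single homoharringtonine arrays the SD of the share was 0.117. For single named genes all arrays were used. The log2 change from vehicle was 2.63 with bleomycin alone and 2.9 with homoharringtonine for Mmp12, and -3.38 and -3.35 for Lrat. Spp1 went from 4.54 to 3.34, Timp1 from 3.68 to 1.78, Arg1 from 3.64 to 0.78, and Itgam from 1.66 to 0.03.

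**Figure D5:**
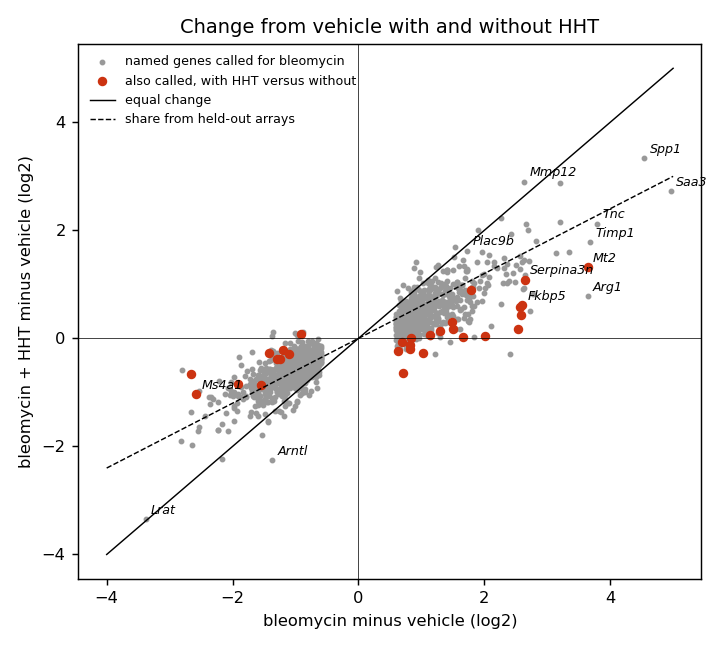
Log2 change from vehicle with homoharringtonine against that with bleomycin alone, for named genes called for bleomycin (grey) and those also called between homoharringtonine and bleomycin alone (red). The solid line marks an equal change and the dashed line a share of 0.6. Spp1 lies at 4.54 and 3.34, Arg1 at 3.64 and 0.78, and Lrat at -3.38 and -3.35.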

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

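No call of a list, or of a gene that the naming rule singled out, turned direction in the settings run. The share of the bleomycin change remaining stayed between 0.536 and 0.655, within its SD of 0.117 over single arrays. Of 135 genes that the naming rule singled out and limma called for bleomycin against vehicle, 102 to 135 kept the call in each setting. For homoharringtonine against bleomycin 0 to 24 of 24 did, and against vehicle 4 to 49 of 49. The naming rule favours strong genes, and these counts do not cover all 1529, 30 and 143 named genes called. Without single replicates the count of probe sets called ranged from 1136 (without vehicle replicate 3) to 3396 (without bleomycin replicate 1) for bleomycin against vehicle, from 0 to 181 (without bleomycin replicate 1) for homoharringtonine against bleomycin, and from 7 (without vehicle replicate 3) to 257 (without bleomycin replicate 1) for homoharringtonine against vehicle. Over all genes of the naming rule and all settings the call was the same 6180 times, gained 97 times and lost 698 times. A fit without an array has 5 residual degrees of freedom, which lowers the power by construction. This alone does not explain the 181 calls without bleomycin replicate 1. The fit on the 6 arrays of the groups compared, with 4 degrees of freedom, called 0 for homoharringtonine against bleomycin. For bleomycin and homoharringtonine against vehicle it called 2374 and 144. The main fit pools the spread of all groups, and array weights were 1.1 to 1.46 for vehicle and 0.81 to 0.99 for other arrays. With these weights 16 were called for homoharringtonine against bleomycin. How far the 39 calls rest on the vehicle spread was not tested.

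No label says that the same replicate numbers pair the mice. The deviations of same-numbered arrays correlated between -0.14 and 0.09, and 2 of 9 arrays correlated best with their own number. No pairing was seen in this, though a shared litter or day cannot be excluded. With a replicate block the counts were 2175, 0 and 22. At an absolute log2 fold change of at least 1 besides the threshold, 975 were called for bleomycin against vehicle and 105 for homoharringtonine against vehicle. With an unadjusted p under 0.05 and that fold the counts were 1329, 339 and 631. Array weights gave 16 for homoharringtonine against bleomycin and 385 for homoharringtonine against vehicle, and without the dimmest 25% of probe sets these were 69 and 358. With named genes only, the counts were 1839, 706 and 1019, and with the mean of the probe sets of a gene 1840, 705 and 1019. With the adjustment over all probe sets 1529, 30 and 143 named genes were called, and the fit on named genes alone differs from it in its variance prior as well as in the genes adjusted over. The authors' deposited tables listed 2074 for bleomycin against vehicle and 116 for homoharringtonine against bleomycin. For the lists, an estimated correlation gave 0 calls in each comparison in place of 14, 12 and 10, and fry called 22 for bleomycin against vehicle and 16 for homoharringtonine against vehicle. Where no construction is named, the cause was not tested. Quantile normalization and median centring moved no array median by more than 0.049 log2. Signal over background was not used here, so what it limits is unknown.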

Other observations

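Several lists not yet described held few named members. Of 5 measured dendritic cell and antigen presentation genes 1 rose and 2 fell with bleomycin (2 and 3 adjusted over the list alone), with a camera adjusted p of 0.927. Both measured genes of the mast cell and eosinophil list, Kit and Hdc, fell (2 adjusted over the list alone). The mesothelial list had 1 rise and 1 fall among 3 measured (1 and 2 adjusted over the list alone), lymphatic endothelium 1 rise among 3 (2 adjusted over the list alone), and Wnt, Hippo and Notch targets 1 rise and 1 fall among 3 (2 and 1 adjusted over the list alone). All 3 measured translation factor and ribosome biogenesis genes rose, with Myc 2.38-fold higher (3 adjusted over the list alone). Of the immediate early list Jun fell and Junb rose, of the T cell list Bcl11b fell, and adipose genes had 1 rise and 1 fall among 4 (1 and 1, 1, and 1 and 3 adjusted over the list alone). Of 9 circadian clock genes 4 rose and 2 fell (4 and 3 adjusted over the list alone), with a camera adjusted p of 0.531. Of the lists for sterol and fatty acid synthesis, skeletal muscle, erythroid cells and thymus 0 genes were named here. In the plasma cell gene Jchain the log2 signal was 5.73 ± 0.17, 5.79 ± 1.43 and 7.67 ± 0.76 (SD, n = 3 each) in vehicle, bleomycin and homoharringtonine lungs, and this difference did not pass the threshold. Jchain was singled out after its values were seen.

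With 10 splits of 6 arrays no share under 0.05 can be had. Only the real split, 1 of 10, gave as many calls in each comparison, with 3218, 39 and 209 against a highest other count of 0. Every other split mixed arrays of both groups, which puts their difference into the spread within groups. Counts near 0 were therefore likely beforehand, and the splits add no support to the calls. The tests of the locus and of the clock genes, and the test against random lists, were chosen only after the result was seen. The spread measure for the locus was also redefined after a value was seen, and the locus, clock, unseen marker and left-out pair results were read more cautiously than the bounds set for them, for the reasons given with each.

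The 3 Plac9b and 3 Tmem254b probe sets lie between 25887508 and 26207071 on chromosome 14 and rose by 2.1 log2 on average in bleomycin lungs and 1.99 in homoharringtonine lungs. Copies of the same gene differed in their change by at most 0.17, as probe sets reading the same transcripts would, so the 6 are not separate measurements. Their median spread over the 6 instilled mice, 0.18, lay at percentile 0 of 93 probe sets that rose as much, whose median was 0.73. A candidate explanation is a copy number or stock difference between the vehicle mice and the instilled mice, and a bleomycin response that homoharringtonine left alone, with a difference of -0.11, is another. These cannot be told apart, because the locus was picked for this evenness and the labels give no litter or stock, and a genotype of the mice would decide it.

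Of 9 measured circadian clock genes Per2 rose and Arntl and Npas2 fell with homoharringtonine against vehicle (5 and 3 adjusted over the list alone), with a camera adjusted p of 0.395, so the list as a whole was not called. The mean log2 signal of Per1, Per2, Per3 and Dbp minus that of Arntl and Npas2 was taken on each array, without centring on vehicle. This value was 0 ± 0.25 in vehicle, 1.73 ± 0.49 in bleomycin and 2.56 ± 0.25 in homoharringtonine lungs (SD, n = 3 each). For all 6 genes the homoharringtonine and vehicle arrays did not overlap. The 6 genes were picked after their values were seen, Per1, Per3 and Dbp did not pass against vehicle (adjusted p 0.104, 0.126 and 0.14), and with bleomycin alone the log2 change of Dbp was -0.1 (adjusted p 0.863). The difference of 2.56 is consistent with lungs taken at another hour of the day, and with an effect of the treatments on the clock. These cannot be told apart, because no hour of collection is in the labels.

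Among the genes lower with homoharringtonine than with bleomycin alone, Fkbp5, Tat, Pdk4, Sgk1, Mt2 and Map3k6 are known to be raised by glucocorticoids. Other markers seen beforehand, Mt1, Per1, Ddit4, Cdkn1a, Il1r2 and Lcn2, did not pass in that comparison, with adjusted p from 0.0712 (Mt1) to 0.774 (Lcn2). The marker list held 32 genes whose values had not been seen. Only 9 of these carried a name and were measured, so the authors had listed them as changed on these same arrays. Of the 9, 8 rose with bleomycin and had lower values with homoharringtonine, against 40.1% of all named genes with both signs. Camera on the 9 between homoharringtonine and bleomycin alone, against the other named genes, those that fell included, gave an unadjusted p of 0.00256. With an estimated correlation camera gave p = 0.04. None of the 8 passed the threshold between homoharringtonine and bleomycin alone, and 96.9% of the other named genes that rose also had lower values, so a stronger glucocorticoid response in the bleomycin mice than with homoharringtonine cannot be told apart from the lower values of risen genes at large. The 8 kept a median share of 0.416 of their rise against 0.492 in other genes that rose, and 22.9% of random lists were as low, so a lowering beyond that of other genes that rose stays open. With probe sets chosen without 1 bleomycin and 1 homoharringtonine array, the left-out pair showed a median of 0.507 of the change, which passes the bound of 0.5 set against chance in the shared arrays by less than its range of 0.377 to 0.695, so chance may hold part of the size.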
